A study of Mus musculus with 6 samples.

How the data were processed

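Gene expression was measured in cultured mouse myoblasts with 1-colour Agilent whole-genome arrays, 3 for cells treated with transforming growth factor beta (TGFb) for 4 days and 3 for untreated cells. Per the labels' protocols, the cells were sorted by flow cytometry, RNA was purified with an RNeasy Micro kit, and it was labelled with the dye Cy3 using an Agilent SureTag kit. The labels call the samples independent experiments and state no pairing between the groups. The names of the scanner files give both untreated replicate 1 and untreated replicate 2 the number 2, so whether these arrays come from different cultures is not certain. If they shared a culture, the untreated group would hold 2 independent samples and the SEs and p-values would be too small.

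The authors deposited one scanner file per array, which holds the intensity of each spot. Per the file headers, these intensities were extracted with Agilent Feature Extraction 10.7.3.1, which subtracted the background and removed spatial trends within each array. Spots close to background carry substitute values set by that software, so differences between dim probes are less certain than differences between bright ones. The authors also deposited 1 table of normalized log2 values for the 6 arrays. Its columns had medians between 6.99 and 7.00 and each correlated best with the log2 mean signal of its own array (r across probes of 0.986 to 0.987). The values rise with the scanner signal and are on a log2 scale by that comparison, but the normalization behind them is not given in the sources used here. The table served as an alternative, not as the main source.

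For the main values, spots flagged as outliers (176 to 365 spots per array) and control spots were left out. Processed intensity was converted to log2 and each array's 75th percentile over the non-control spots was subtracted. Spots of the same probe were averaged. A probe was tested if it was well above background on at least 3 of the 6 arrays, whatever the group, and each gene was represented by its probe with the highest mean over all 6 arrays. This left 21999 genes. Gene names came from the arrays' own annotation. They were updated through a RefSeq gene table (assembly GRCm38.p6) for the 26300 of 55681 probes whose accession it held, which changed 2839 names. The arrays' probe coordinates refer to mm9, so no coordinate of that table was used.

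The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, TGFb minus untreated). P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Lists of genes, 34 in all, were fixed before the data were examined and tested with limma's camera at a preset correlation between genes of 0.01. Their p-values were adjusted over the 34 lists, and each was tested again with a correlation estimated from the data. That second test also rests on the few residual degrees of freedom of the fit, so a lost call need not mean a higher correlation. For the matrix glycoprotein, interferon response and collagen-processing lists the estimates were -0.0108, -0.0248 and 0.000502, below the preset. For a gene with no probe well above background on any array of one group, the change is given as a lower bound. The bound is the bright group's mean over the dim group's mean of, per array, the higher of the lowest well-above-background signal and the probe's own signal.

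The rule for naming genes was also fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among genes past the threshold that were well above background on all 6 arrays and whose groups did not overlap, leaving out clone and predicted names. It adds up to 5 genes per direction that were below background in one group and above it on all arrays of the other. From each list it takes the 4 tested members with the smallest adjusted p. It also takes 16 genes whatever their values, among them Acta2, Pax7, Myod1 and Mki67. Other genes that are named were chosen after their values were seen, and the text says so.

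The file headers showed that the arrays were scanned on 2 days. TGFb replicate 1 and untreated replicates 1 and 2 were scanned on day 1, and TGFb replicates 2 and 3 and untreated replicate 3 on day 2. Each day thus held both groups, and scan day was added as a term in a second fit after the data were seen. Its counts are given beside those of the fit without it for all genes and for the lists that camera called, a gene said to pass with scan day as a term did not pass over all genes without it, and the called lists come with the median differences within day 1 (1 TGFb array, 2 untreated) and within day 2 (2 TGFb arrays, 1 untreated). The arrays lay on 4 slides, 2 of which held 1 array of each group.

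The fits were tested on simulated data with the spread of these arrays and 50 genes changed at each of several folds, over 21865 genes. With the measured scan-day differences left in, the fit without a scan-day term recovered 0% of the genes changed 4-fold and 0% of those changed 8-fold. The simulation changed few genes and none by more than 8-fold, which makes the adjusted threshold harder to pass. On the real arrays that fit called 302 genes, with absolute log2 changes down to 1.485. The 0% therefore does not give its sensitivity there. A scan-day term raised this to 8% at 2-fold, 66% at 4-fold and 70% at 8-fold, with 6 false calls. Without scan-day differences in the simulation, the fit without the term recovered 68% at 4-fold and 82% at 8-fold, with 7 false calls. There the fit with the term recovered less, 48% at 4-fold and 68% at 8-fold, with 2 false calls. Precision is limited by the number of arrays. Alternatives covered background correction by normexp (offset 50), quantile normalization, scaling to the median, the authors' table, other filters on dim probes, other rules for a gene's probe, other variance models, array weights, slide and replicate number as blocks, and each replicate left out in turn. All splits of the 6 arrays into 3 and 3 were fitted in the same way.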

Results

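The series profiled RNA from myoblasts, the precursor cells of skeletal muscle fibres, taken from 3-month-old male C57BL/6 mice. It compared cells exposed for 4 days to TGFb, a secreted growth factor with a central role in fibrosis, with untreated cells. Each group held 3 arrays, which the labels call independent, although the file names number untreated replicates 1 and 2 alike. The 75th percentile of processed intensity lay between 879 and 1578 across arrays, and 50.9% to 55.8% of probes were well above background on each. The most saturated array had 77 saturated spots among 59305.

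The first principal component (72.4% of the variance) separated the arrays by scan day, and the second (16.3%) separated treated from untreated arrays. Arrays of different groups scanned on the same day correlated at 0.97 to 0.977 across genes, against 0.919 to 0.929 for arrays of the same group scanned on different days. These correlations are across genes, which are not independent replicates.

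**Figure D1:**
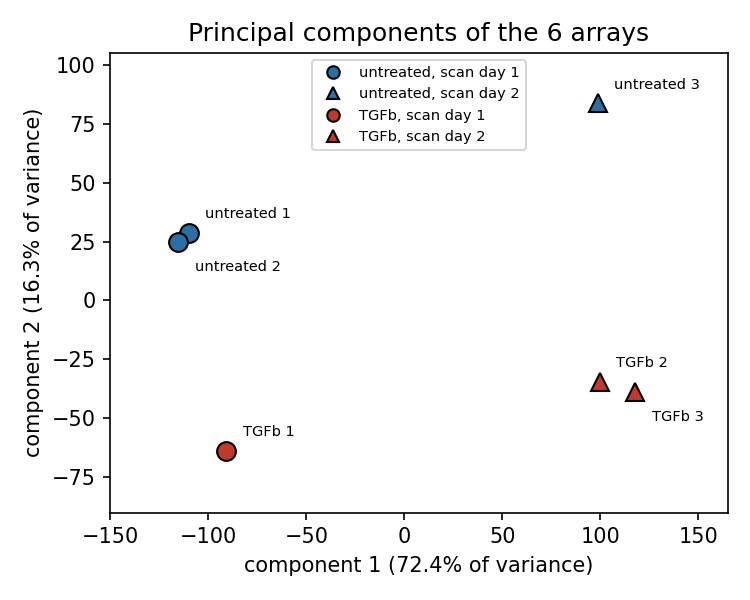
Positions of the 6 arrays on the first (72.4% of variance) and second (16.3%) principal components of log2 expression, with colour for group and marker shape for scan day. Arrays scanned on day 1 lie on the left and those scanned on day 2 on the right, while the 3 TGFb arrays lie below the 3 untreated arrays.

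After TGFb, some matrix, TGFb feedback and myofibroblast genes rose (4 of 26, 3 of 17 and 3 of 19 tested) and 10 of 39 sarcomere genes fell; the shifts of these lists as wholes were lost with an estimated correlation (adjusted p = 0.125 to 0.328). Smoc2, a secreted calcium-binding matrix protein, showed the largest rise among genes well above background on all 6 arrays (log2 fold change 6.53 ± 0.26, SE, n = 3 per group; limma adjusted p = 0.00244). Ccn2, the matricellular connective tissue growth factor, rose by 3.06 ± 0.24 (adjusted p = 0.0113). Myf6, a myogenic transcription factor, fell by 4.54 ± 0.51 (adjusted p = 0.0202), and Myh4, a fast-fibre myosin heavy chain, fell by 4.59 ± 0.48 (adjusted p = 0.017). In each of these 4 genes all TGFb arrays lay on one side of all untreated arrays.

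Among 21999 genes tested, 151 rose and 151 fell, and all 302 changed by at least 2-fold, with a median absolute log2 change of 2.69. When scan day was a term, 1010 genes rose and 1229 fell, of which 721 and 860 changed by at least 2-fold. All 302 genes of the first fit were in the second with the same direction. Each also had the same sign within both scan days and within both slides that held the 2 groups, which their choice on the same arrays favours; over all genes, 67.9% had the same sign on both days. With slide as a block, 361 genes rose and 408 fell. That fit draws on the 2 slides that held both groups, since the other slides held a single array each. It leaves few residual degrees of freedom. Across all genes, the fold changes of the 2 scan days, which share no array, correlated with r = 0.596 and rho = 0.513, and those of the 2 slides with r = 0.604. Each of these slides lay within a single scan day. The slide signs and correlation therefore reuse arrays behind the scan-day values and are no separate check. The groups did not overlap for 3951 genes (17.96%). Chance gives 10% for arrays that differ in nothing but the group, and these arrays also differed by scan day, so that value is only a rough guide. The count without a scan-day term rested on single arrays: limma called 96 genes without TGFb replicate 1, 0 without replicate 2, 2 without replicate 3, 0 without untreated replicate 1, 0 without replicate 2 and 196 without replicate 3. Leaving out TGFb replicate 1 or untreated replicate 3 put the rest of that group on a single scan day. Those 2 counts therefore mix group with day more (3915 and 4087 genes at an unadjusted p under 0.05 in limma). The 3 fits with 0 calls had 1645, 1468 and 1470 genes at an unadjusted p under 0.05, and called 1744, 673 and 599 genes with scan day as a term.

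Other large rises were in genes of diverse functions, and log2 fold changes within day 1 and within day 2 are given for each. Acsbg1, an acyl-CoA synthetase, rose by 5.32 ± 0.28 (4.92 and 5.72), and Gprin3 by 5.20 ± 0.38 (5.01 and 5.13). Anxa8, an annexin, rose by 4.95 ± 0.24 (4.89 and 5.10) and Ccbe1, a secreted regulator of lymphatic growth, by 4.89 ± 0.31 (5.38 and 4.49). Timp3, an inhibitor of matrix metalloproteinases, rose by 4.56 ± 0.27 (4.32 and 4.57). The calcium-activated chloride channel Ano1 rose by 4.39 ± 0.42 (4.18 and 4.02), the matrix glycoprotein Tnc by 4.33 ± 0.46 (4.12 and 4.64) and the adhesion molecule Alcam by 4.02 ± 0.34 (3.77 and 3.83). Their adjusted p-values lay between 0.00537 for Anxa8 and 0.0172 for Tnc.

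The largest falls included genes of muscle. Crym, a thyroid hormone-binding crystallin, changed by -4.67 ± 0.43 (adjusted p = 0.0152) and Ckmt2, the sarcomeric mitochondrial creatine kinase, by -4.66 ± 0.30 (adjusted p = 0.00919). Casq1, the calcium-storage protein of fast fibres, changed by -4.01 ± 0.63 (adjusted p = 0.0482). The myostatin gene Mstn changed by -3.60 ± 0.50 (adjusted p = 0.0352) and Fgf6, a growth factor of the muscle lineage, by -3.55 ± 0.52 (adjusted p = 0.0389). Outside muscle, the neutrophil chemokine Cxcl5 changed by -4.47 ± 0.34, the long noncoding RNA Meg3 by -4.36 ± 0.34 and the receptor Vipr2 by -4.01 ± 0.26. Within scan days these 8 genes ranged from -5.19 for Crym on day 2 to -2.59 for Mstn on day 1. Casq1 changed by -3.51 ± 0.17 with scan day as a term (adjusted p = 0.00158).

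**Figure D2:**
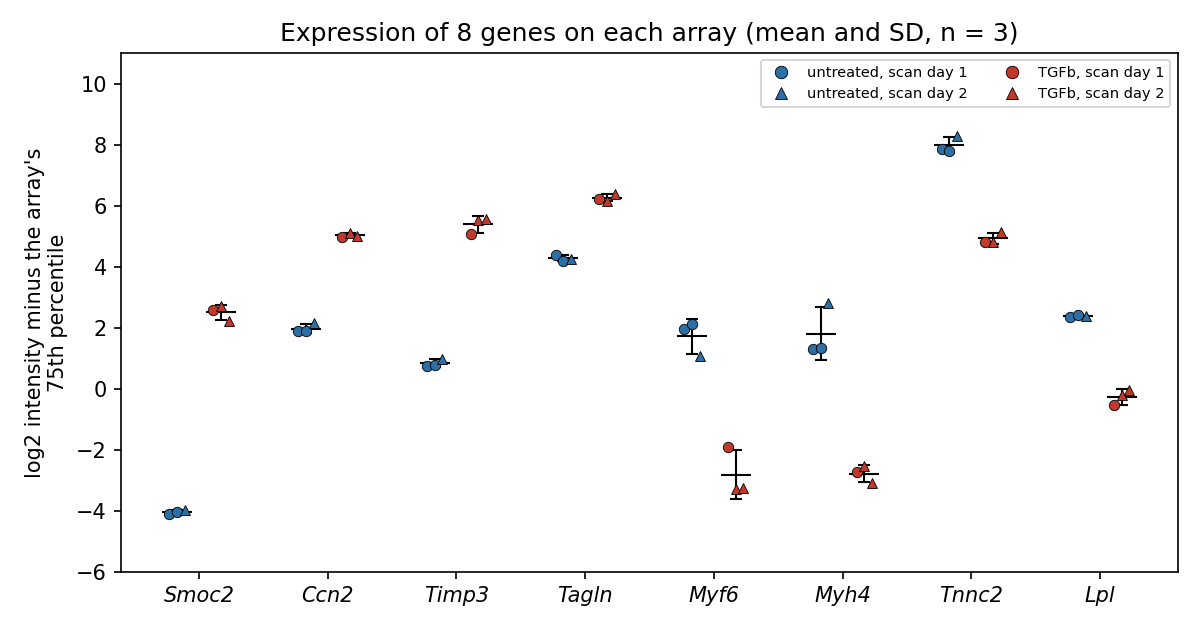
Log2 intensity minus the array's 75th percentile for 8 named genes on each of the 6 arrays. Points are single arrays, with colour for group and shape for scan day, and black bars give the mean and SD of each group (n = 3). For each gene the 3 TGFb arrays lie on one side of the 3 untreated arrays, as for Smoc2 with means of 2.50 and -4.03.

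Some genes were well above background on all 3 arrays of one group and on none of the other, so that only a lower bound of the change could be had. Ucma, a secreted cartilage matrix protein, was at least 30.2-fold higher after TGFb, and the metalloproteinase Adamts16 at least 17.4-fold higher. The cytokine receptor gene Il21r was at least 9.59-fold, the cornified-envelope gene Sprr2e at least 8.76-fold and the cartilage protein Cilp at least 8.14-fold higher. In the other direction, Mlip, a lamin-interacting protein of muscle, was at least 9.47-fold lower, the basement membrane gene Frem1 at least 8.70-fold lower, and Pf4, Upk1b and Sag at least 6.00-fold, 5.92-fold and 5.46-fold lower. The probes of the leading genes lie on mm9 at chromosome 17, 14541664 to 14541723 (Smoc2), chromosome 10, 24318281 to 24318340 (Ccn2), chromosome 10, 106930237 to 106930296 (Myf6), chromosome 7, 127329970 to 127330029 (Crym), and chromosome 2, 4906712 to 4906771 (Ucma).

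Genes of the TGFb feedback loop and immediate SMAD targets held 3 of the rises. Of 17 tested, 3 rose, 0 fell and 14 did not pass the test, and 9 rose when adjusted over the list alone. The fit with scan day as a term had 10 that rose and 0 that fell. The list shifted upward against all other genes (camera adjusted p = 6.12e-07, median log2 fold change 0.97; 2.08e-07 with scan day as a term, with medians of 1.15 within day 1, 0.97 within day 2, and 1.08 and 0.86 within slides). That call was lost with an estimated correlation (adjusted p = 0.125, and 0.337 with scan day as a term). The genes that rose were Ccn2, Ltbp2 (3.77 ± 0.37, adjusted p = 0.0152) and Ldlrad4, an inhibitor of TGFb signalling (adjusted p = 0.0152). Ldlrad4 was well above background on 1 of 3 untreated arrays and is given no fold. Pmepa1 and Smad7 passed over the list alone and, over all genes, with scan day as a term, at 2.33 ± 0.17 and 1.60 ± 0.33 (adjusted p = 0.00277 and 0.0423). Without that term their log2 fold changes were 2.79 and 1.90 (adjusted p = 0.105 and 0.184).

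Sarcomere and contraction genes held 10 of the falls. Of 39 tested, 10 fell, 0 rose and 29 did not pass the test, and 26 fell and 1 rose when adjusted over the list alone. Scan day as a term gave 30 that fell and 1 that rose. The riser was Myl2, a ventricular and slow-fibre myosin light chain chosen here after its values were seen (1.10, adjusted p = 0.0172 with that term). The median log2 fold change was -1.27 (camera adjusted p = 1.52e-21; 5.28e-20 with scan day as a term), -1.27 within day 1, -1.38 within day 2, and -1.20 and -1.53 within slides. Again the call was lost with an estimated correlation (adjusted p = 0.125, and 0.337 with scan day as a term). Tnnc2, the fast-fibre troponin C, changed by -3.06 ± 0.27 (adjusted p = 0.0152) and Myh8, the perinatal myosin, by -2.43 ± 0.25 (adjusted p = 0.0161). Mybpc2, a fast myosin-binding protein, was below background on all TGFb arrays and at least 2.75-fold lower (adjusted p = 0.0214). The embryonic myosin Myh3 had a log2 fold change of 0.02 ± 0.43 (adjusted p = 0.985), with means of 8.53 and 8.51. The second Myh3 probe had a value of -0.99, and -1.17 with scan day as a term.

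**Figure D3:**
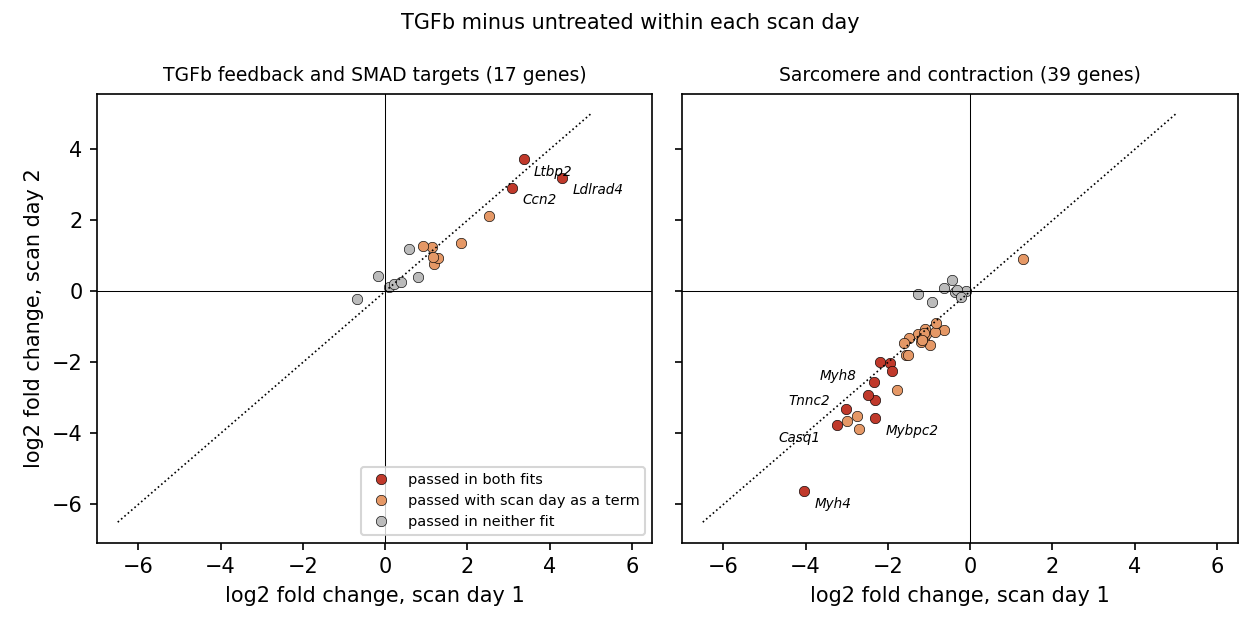
Log2 fold changes (TGFb minus untreated) within scan day 1 (x axis) and within scan day 2 (y axis) for the 17 tested genes of the TGFb feedback list (left) and the 39 of the sarcomere list (right). Each point is a gene, coloured by whether it passed the test, and the dotted line marks equal change; Ccn2 lies at 3.07 and 2.92, and Myh4 at -4.04 and -5.62.

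Regulators of myogenic differentiation also shifted downward (median -0.46, camera adjusted p = 3.23e-04; -0.69 within day 1 and -0.88 within day 2). That call was lost with an estimated correlation (adjusted p = 0.304, and 0.426 with scan day as a term). Of 23 tested, 1 fell, 0 rose and 22 did not pass, and 7 fell and 1 rose when adjusted over the list alone. Adding scan day (camera adjusted p = 1.63e-05) gave 11 that fell and 1 that rose, the latter being Igfbp5, chosen after its values were seen. Myf6 was the gene that fell. Igf2, Mef2c and Smyd1 passed over the list alone and, over all genes, with scan day as a term, at -2.01, -1.74 and -1.80 (adjusted p = 0.00277, 0.0097 and 0.0244). The differentiation factor Myog had a log2 fold change of -0.46 ± 0.25 (adjusted p = 0.582).

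Identity genes of satellite cells and myoblasts showed no shift (21 tested, 0 rose and 0 fell, also when adjusted over the list alone; camera adjusted p = 0.811). Pax7, the satellite cell transcription factor, had a log2 fold change of 0.08 ± 0.26 (adjusted p = 0.912). Myod1 had one of 0.03 ± 0.69 (adjusted p = 0.987), with -0.59 within day 1 and -0.48 within day 2. Myf5 was well above background on 1 of the 6 arrays and was not tested. Of this list 3 genes rose and 3 fell with scan day as a term, among them Pax3 (0.88, adjusted p = 0.0217), Ncam1 (1.28, adjusted p = 0.0107) and Chrdl2, which was below background on all TGFb arrays and is given no value. Met, Dag1 and Fgfr4 were the others, chosen after their values were seen. The probes of Ncam1 disagreed in direction.

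Myofibroblast and smooth muscle genes shifted upward as a list (median 0.64, camera adjusted p = 2.05e-04; 0.55 within day 1 and 0.65 within day 2). The call was lost with an estimated correlation (adjusted p = 0.328, and 0.426 with scan day as a term). Of 19 tested, 3 rose, 0 fell and 16 did not pass, and 7 rose and 1 fell when adjusted over the list alone. Scan day as a term gave 8 that rose and 2 that fell (camera adjusted p = 0.00192), Des and Smtn, the latter chosen after its values were seen. The collagen-binding integrin Itga11 rose by 3.41 ± 0.36 (adjusted p = 0.017), the calponin Cnn1 by 2.40 ± 0.29 and the actin-binding protein Tagln by 1.98 ± 0.24 (both adjusted p = 0.0234). Smooth muscle actin, Acta2, was bright in both groups (means of 8.67 and 8.28) and its log2 fold change of 0.38 ± 0.23 did not pass the test (adjusted p = 0.627). The muscle intermediate filament gene Des fell with scan day as a term (-1.28, adjusted p = 0.00998).

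Matrix glycoproteins and proteoglycans shifted upward as a list (median 0.60, camera adjusted p = 0.00986; 0.61 within day 1 and 0.36 within day 2). This call was lost with an estimated correlation (adjusted p = 0.239, and 0.418 with scan day as a term). Of 26 tested, 4 rose, 0 fell and 22 did not pass, and 6 rose and 2 fell when adjusted over the list alone. The fit with scan day as a term had 10 that rose and 3 that fell (camera adjusted p = 0.0141). The 3 were Dcn, Fbn2 and Ogn, of which Fbn2 and Ogn were chosen after their values were seen. Besides Tnc, the risers were Fbln2 (2.59 ± 0.28), Spp1 (2.44 ± 0.28) and Thbs1 (3.51 ± 0.46), with adjusted p-values of 0.0192, 0.0202 and 0.0282. Fn1, the fibronectin gene, passed over the list alone and, over all genes, with scan day as a term (1.42 ± 0.16, adjusted p = 0.00777), against 1.84 ± 0.53 and an adjusted p of 0.236 without it.

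The collagen list shifted upward at a camera adjusted p of 0.0485 (median 0.30; 0.32 within day 1 and 0.26 within day 2), which did not hold with scan day as a term (adjusted p = 0.127) or with an estimated correlation (adjusted p = 0.328). Of 18 tested, 2 rose, 0 fell and 16 did not pass, and 5 rose and 1 fell when adjusted over the list alone, as many as with scan day as a term. Col8a2 rose by 3.38 ± 0.30 (adjusted p = 0.0152) and Col11a1, below background on all untreated arrays, was at least 4.13-fold higher (adjusted p = 0.0162). The main fibrillar collagen genes Col1a1 and Col1a2 passed over the list alone and, over all genes, with scan day as a term, at 1.80 ± 0.20 and 1.04 ± 0.15 (adjusted p = 0.0073 and 0.0153). Without it their values were 2.34 ± 0.67 and 0.98 ± 0.25 (adjusted p = 0.227 and 0.175). Col6a2, a collagen VI chain, passed with that term in the other direction (-1.65, adjusted p = 0.00405).

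Collagen-processing enzymes shifted upward as a list (21 tested; 1 rose, 0 fell; 3 rose when adjusted over the list alone; median 0.15, 0.06 within day 1 and 0.38 within day 2). The camera adjusted p was 0.0341, 0.0287 with scan day as a term (5 rose, 0 fell) and 0.295 with an estimated correlation. The crosslinking enzyme Lox rose by 3.23 ± 0.41 (adjusted p = 0.0252). Loxl2, Loxl3 and Plod2 passed with scan day as a term, at 1.47, 1.05 and 1.04 (adjusted p = 0.0075, 0.0138 and 0.0308). Matrix proteases and their inhibitors shifted upward too (19 tested; 1 rose, 0 fell; 2 rose when adjusted over the list alone; median 0.27, 0.23 within day 1 and 0.44 within day 2; camera adjusted p = 0.014, 0.0158 with scan day as a term). The adjusted p was 0.37 with an estimated correlation. The inhibitor gene Timp3 rose. With scan day as a term Timp1 (2.38 ± 0.14, adjusted p = 0.00198) and the plasminogen activator Plat (0.72, adjusted p = 0.03) also rose, and the metalloproteinase Adam19 fell (-1.29), the last chosen after its values were seen.

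Growth factors and kinase receptors shifted upward as a list (30 tested; 3 rose, 0 fell; 8 rose and 3 fell when adjusted over the list alone). The median was 0.67, with 0.46 within day 1 and 0.80 within day 2 (camera adjusted p = 1.10e-04, and 0.00223 with scan day as a term, where 11 rose and 3 fell). With an estimated correlation the adjusted p was 0.295. Vegfc, a lymphatic growth factor, rose by 2.38 ± 0.27 (adjusted p = 0.0202) and Angptl4 by 1.91 ± 0.24 (adjusted p = 0.0252). Fgf2, below background on all untreated arrays, was at least 2.86-fold higher (adjusted p = 0.024). In the cytokine list (17 tested; 3 rose, 1 fell; 7 rose and 4 fell when adjusted over the list alone; camera adjusted p = 0.39), Il6 rose by 3.15 ± 0.38 and Il11 by 2.34 ± 0.23, while Cxcl5 fell. Cxcl14, below background on all untreated arrays, was at least 2.47-fold higher.

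Cell cycle and replication genes shifted downward by a small amount (median -0.36, camera adjusted p = 0.00104; -0.33 within day 1 and -0.51 within day 2), a call lost with an estimated correlation (adjusted p = 0.328). None of 38 passed the gene-level test in limma, 0 also when adjusted over the list alone, against 3 that fell with scan day as a term (camera adjusted p = 2.69e-05). Those 3 were E2f2 (-1.10, adjusted p = 0.0145), the proliferation marker Mki67 (-0.75, adjusted p = 0.0284) and Top2a, the last chosen after its values were seen. Cdkn1a, a cyclin-dependent kinase inhibitor that rises as myoblasts leave the cycle, passed with scan day as a term at -0.94 (adjusted p = 0.0366), against -1.05 and 0.203 without it. The other 2 Cdkn1a probes had values of -0.15 and 0.08 with that term.

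Mitochondrial respiration genes shifted downward (27 tested; 0 rose, 1 fell; 4 fell when adjusted over the list alone; median -0.21, -0.38 within day 1 and -0.70 within day 2). The camera adjusted p was 4.23e-04, and 3.50e-09 with scan day as a term (0 rose, 7 fell), but 0.427 with an estimated correlation. Cox6a2, the muscle isoform of a cytochrome oxidase subunit, changed by -2.37 ± 0.25 (adjusted p = 0.0169). Cox8b and Cox7a1, which are also muscle isoforms, passed with scan day as a term (-1.35 and -1.70, adjusted p = 0.00606 and 0.00635). So did Uqcrc1, which is not a muscle isoform (-1.20, adjusted p = 0.00854). Interferon response genes shifted downward as well (25 tested; 0 rose, 0 fell; 2 fell when adjusted over the list alone; median -0.57, -0.47 within day 1 and -0.58 within day 2; camera adjusted p = 0.00369, 0.00159 with scan day as a term). With an estimated correlation the adjusted p was 0.234. There were 6 members that fell with scan day as a term, among them Psmb9 (-1.31), Ifit3 (-1.18) and Irf7 (-0.93).

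Lists of other cell types that a muscle sort could hold gave the following. Adipocyte genes shifted downward (16 tested; 0 rose, 3 fell; 1 rose and 6 fell when adjusted over the list alone; median -0.36, -0.77 within day 1 and -0.65 within day 2; camera adjusted p = 0.014, and 0.00841 with scan day as a term, where 1 rose and 6 fell). The adjusted p was 0.4 with an estimated correlation. The members that fell were Lpl (-2.65 ± 0.26), Plin4 (-1.72 ± 0.27) and Slc2a4 (-2.51 ± 0.39), and lipoprotein lipase and the glucose transporter Slc2a4 are also genes of muscle. Fibroblast and fibro-adipogenic progenitor markers did not shift as a list (18 tested; 1 rose, 0 fell; 2 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.971). Smoc2 was the riser, and Pdgfra had a log2 fold change of -0.07 ± 0.47 (adjusted p = 0.964). With scan day as a term 2 members of the list rose and 3 fell, the latter being Thy1, Fap and Dcn at -1.55, -1.64 and -2.57. These markers were well above background for 16 to 18 of 24 genes on every array. The detected numbers were 7 or 8 of 18 endothelial genes, 7 to 9 of 23 macrophage and leukocyte genes, 9 of 12 pericyte genes, and 7 Schwann cell genes of 14 on each TGFb array against 8 or 9 on the untreated ones. None of those 4 lists shifted (camera adjusted p = 0.102, 0.971, 0.785 and 0.971). When adjusted over the list alone 2, 0, 1 and 1 members fell and 0, 0, 0 and 1 rose. With scan day as a term Vwf (-1.30) and Ecscr (-1.18) of the endothelial list fell, and Rgs5 (1.57) of the pericyte list, Egr2 (1.95) and Mbp (0.98) of the Schwann cell list and Laptm5 (1.00) of the macrophage list rose, the last chosen after its values were seen. The falls that passed without that term were Abcc9 in the pericyte list (-2.63 ± 0.26) and Foxd3 in the Schwann cell list, below background on all TGFb arrays and at least 3.03-fold lower.

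The remaining lists did not shift by camera. TGFb ligands and receptors (21 tested; 0 rose, 1 fell; 1 rose and 2 fell when adjusted over the list alone) had Mstn as the gene that fell, and Inhba, an activin subunit, passed with scan day as a term (3.67 ± 0.25, adjusted p = 0.00238). In the BMP and Id list (19 tested; 2 rose, 0 fell; 2 rose and 1 fell when adjusted over the list alone), the BMP antagonist Grem1 rose (3.49 ± 0.29). The Wnt list (25 tested; 1 rose, 1 fell; 5 rose and 1 fell when adjusted over the list alone) held Wnt5a, which rose by 2.08 ± 0.24, and the Wnt antagonist Sfrp2, which fell by 2.63 ± 0.34. Of the epithelial to mesenchymal transition regulators (18 tested; 0 rose, 0 fell; 1 rose when adjusted over the list alone; camera adjusted p = 0.0549), Sox4 passed with scan day as a term (1.31 ± 0.14, adjusted p = 0.00671). In the cartilage, bone and tendon list (19 tested; 1 rose, 0 fell; 4 rose and 2 fell when adjusted over the list alone) Cilp rose, in the integrin list (20 tested; 1 rose, 0 fell; 2 rose and 1 fell when adjusted over the list alone) Itga11 rose, and in the oxidative stress list (21 tested; 1 rose, 0 fell; 1 rose when adjusted over the list alone) the NADPH oxidase Nox4 rose by 2.33 ± 0.30. The glycolysis list (23 tested; 0 rose, 1 fell; 2 fell when adjusted over the list alone) held Pgam2, the muscle phosphoglycerate mutase, which changed by -2.43 ± 0.37, and the cholesterol synthesis list (21 tested; 0 rose, 1 fell; 1 fell when adjusted over the list alone) held Dhcr7, at -1.99 ± 0.28. No member passed in limma in the SRF and YAP, cell cycle inhibitor, Notch, unfolded protein response and ribosomal lists (18, 22, 19, 24 and 25 tested), and 0 did when adjusted over each list alone. In the fit with scan day as a term 3, 5, 1, 1 and 0 members passed. They were Axl, Ccn1 and Nuak2, then Gadd45b, Cdkn2b, Cdkn1a, Cdkn1c and Cdkn2c, then Jag1, then Atf3, and of these Nuak2, Cdkn1c and Cdkn2c were chosen after their values were seen.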

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

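Of the alternatives below, scan day as a term and every alternative run together with that term were added after the data were seen; the rest were fixed before the data were examined. The count of 302 changed genes stayed within 1.5 times under normexp background correction, quantile normalization, both other filters on dim probes, both other rules for a gene's probe, and both other variance models, with 246 to 398 genes. Median scaling gave 101 (54 higher, 47 lower), and all 101 were among the 302. The authors' table gave 3292 (1578 higher, 1714 lower; 1166 of at least 2-fold), which held 299 of the 302. Array weights gave 14008 (7706 higher and 6302 lower, 9212 of at least 2-fold). The TGFb weights were 1.87 and 0.545 for the day 2 arrays against 0.155 for the day 1 array. The untreated weights were 11.1 and 5.05 for the day 1 arrays against 0.112 for the day 2 array. The weighted fit thus largely set day 2 against day 1, and its count does not measure the TGFb effect. With scan day as a term, array weights gave 940 higher and 1196 lower. Slide as a block gave 769 (361 and 408), slide as a random block 4305 (2080 and 2225; 2079 of at least 2-fold), and scan day as a term 2239 (1010 and 1229; 1581 of at least 2-fold). The 302 genes were all called under the last 2. The fit with slide as a block draws on the 2 slides that held both groups. Leaving out 1 replicate gave 0 to 196 changed genes, 0 to 117 higher and 0 to 79 lower; the smaller fits have fewer arrays. Those without TGFb replicate 1 or untreated replicate 3 also hold a group scanned on a single day. Apart from these points, the cause was not tested.

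Whether the replicate numbers pair the samples could not be told. The deviations of same-numbered arrays from their group means correlated at 0.808, -0.716 and 0.691. Scan day was not removed from them, and the sign followed whether the 2 arrays shared a day. With the replicate block, limma called 2 genes (2 higher, 0 lower; 2941 at an unadjusted p under 0.05), against 2528 at that level without it. A replicate block adds terms and removes residual degrees of freedom, whether or not the numbers pair the arrays.

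In the fits with scan day as a term, median scaling gave 566 genes higher and 1272 lower, so that 30.8% of changed genes were higher against 45.1% with the 75th percentile. It moved the median log2 fold change of all genes from 0.04 to -0.15. No filter on dim probes gave 615 and 698, and the table of the authors gave 1561 and 1857. Leaving out 1 replicate gave 147 to 1524 higher and 181 to 1797 lower, with 706, 1744 and 3321 changed genes without TGFb replicates 1, 2 and 3, and 673, 599 and 328 without untreated replicates 1, 2 and 3. Without TGFb replicate 1 or untreated replicate 3, only a single scan day held both groups. The group difference in those fits rests on that day's arrays alone.

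Camera called 7 lists higher and 6 lower, and 12 of the 13 with scan day as a term. With an estimated correlation it called 0 and 0, with or without scan day as a term. The test fry, which asks if a list's genes move one way on balance, called 9 higher and 3 lower, and 13 and 8 with scan day as a term. Array weights left 3 higher and 1 lower, and leaving out 1 replicate gave 3 to 8 higher and 1 to 6 lower, the lowest of both without untreated replicate 3. No filter on dim probes with scan day as a term gave 3 lists higher and 8 lower, against 6 and 6 with the filter. The collagen list had adjusted p-values from 0.00295 with slide as a random block to 0.23 with array weights, and of 0.328 with an estimated correlation (0.426 with scan day as a term).

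Among named genes, 1 passed with the other sign: Myod1 had a log2 fold change of -0.44 in the authors' table (adjusted p = 0.047), against 0.03 in the scanner values, where it did not pass. The signs of Myod1, Pax7 and Myh3 also differed between the fits with and without scan day as a term, and none of the 3 passed in either. Of the named genes, 63 gained a call with scan day as a term, 103 kept their side of the threshold and none lost a call. Leaving out TGFb replicate 2, untreated replicate 1 or untreated replicate 2 ended 63 of their calls in each case. Signal over background limits the dimmest genes, whose values close to the floor set by the scanner software have little order.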

Other observations

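The tests of the scale difference between arrays, of the authors' table and of other splits of the arrays were chosen after the results they measure were seen, as were the gene families and the Lce and Sprr genes described here. The guanylate-binding proteins, GTPases induced by interferon, moved together. When scan day was a term, 8 of 10 tested Gbp genes fell and 0 rose (Fisher's exact test, one-sided, adjusted p = 1.17e-05 over both directions of 234 symbol families of at least 8 genes). This test counts genes as independent, although genes of a family can vary together and all were measured on the same 6 arrays. Its p-value therefore does not measure variation between cultures and can be too small. Gbp6 changed by -3.56, Gbp8 by -2.56 and Gbp11 by -2.02, with a family median of -1.23 within day 1 and -1.63 within day 2. Without a scan-day term 0 of the 10 passed in limma, with a median log2 fold change of -1.69. The signs of the 8 were the same under normexp, quantile normalization, median scaling and the authors' table, which their choice on the same arrays favours. With scan day as a term, 6, 8, 7 and 8 of them passed under these settings in that order.

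Further families stood out in the same test, whose p-values carry the same limit. Of 14 tested Asb genes, which encode ankyrin and SOCS box proteins, 6 fell (adjusted p = 0.0271), and of 11 Myh genes 6 fell (adjusted p = 0.0101), among them Myh1 (-3.29), which is outside the naming rule. Of 15 Klf transcription factor genes 6 rose and 2 fell (adjusted p = 0.0161 for the rise), led by Klf6 (1.31) and Klf2 (1.19). Without a scan-day term 3 Myh genes fell and no Klf or Asb gene passed in limma. Under median scaling 3 of the 8 changed Klf genes still passed, and their signs were kept under each scaling.

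A cluster of cornified-envelope genes on chromosome 3 (mm9) was higher after TGFb in cells sorted as myoblasts. With scan day as a term 7 of 9 tested Lce and Sprr genes rose. Among them were Lce1g (4.57 ± 0.20, SE) and Lce1c (3.13 ± 0.23), which were well above background on all 6 arrays. Without that term 4 passed in limma, and Lce1g did not (adjusted p = 0.0533). Sprr1a and Sprr2e were well above background on 3 TGFb arrays and 0 untreated arrays, so they were tested only through the treated group. Lce1f and Lce1i were so on 3 TGFb arrays and on 1 and 2 untreated arrays. Their untreated arrays alone would not have met the filter of 3 arrays either. Lce1f, Lce1i and Sprr2e were among the 4 that passed without scan day as a term. The filter thus favours the share that rose, and members too dim to test are not counted. Of 20 keratinocyte genes written down before they were tested, 8 were bright enough to test and 3 of these were called higher with scan day as a term (Itgb4, Lor and Pkp1; 1 without it, Pkp1), which does not argue against keratinocytes in the treated cultures. Detection argues only against a large share of keratinocytes and leaves a small one open. Of the 20, 5 were well above background on all TGFb arrays, against 6 on all untreated arrays, and 8 on no TGFb array. Among those 8 were Krt1, Krt15 and Krt17. Krt5 and Krt14 were above it on 1 of 3 TGFb arrays, and Krt10 and Trp63 on all 6 arrays. In the other direction, Krt6a, Ivl and Lgals7 were above it on 1 TGFb array and 0 untreated arrays. Several similar probes might read 1 transcript: the called probes shared 38.3% to 55% of their bases pairwise, which was to count against this. That reading was changed to open after the result was seen, since a transcript can match a probe outside the region of its own probe, and transcript sequences were not analysed here.

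The separation of the arrays by scan day was larger than that by treatment, and its source could lie in the arrays or in the cultures. A difference in intensity scale is argued against, since quantile normalization left 0.926 of the median absolute day difference (0.704 against 0.761). A difference in how single probes respond matches the tables: across 5611 genes with at least 2 tested probes, the day difference correlated at only 0.169 between the 2 brightest probes of a gene, whereas the TGFb effect correlated at 0.656. The day difference also correlated with the probes' GC content (r = -0.382 across 30006 probes), and the TGFb effect did not (r = 0.00655). These values are consistent with a candidate source in labelling or hybridization, but no biological explanation was tested, since the labels do not say which cultures were grown together.

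The authors' normalized table called 3292 genes where the scanner values called 302. A candidate explanation is that the normalization removed much of the difference between scan days. In the table the median absolute day difference was 0.183 of that in the scanner values (0.139 against 0.761), which is what this predicts. By comparison, scan day as a term gave 2239 genes in the scanner values, and 1946 of these were also called in the table. How the table was made is not given in the sources used here.

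Splits of the 6 arrays into groups of 3 are too few for a share under 0.05. Without a scan-day term, 2 of the 10 splits, the real one included, gave at least its 302 genes. The highest of the others gave 10137 and was the split by scan day, which points to a structure of the samples. The remaining 8 gave 0 in limma, with 40 to 311 genes at an unadjusted p under 0.05. Among the fits with scan day as a term, 1 of 9 splits that keep the same numbers of arrays per day, the real one, gave 2239, and the highest of the others gave 0 (212 to 1087 genes at an unadjusted p under 0.05).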
